A study of Homo sapiens with 26 samples.

How the data were processed

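RNA was sequenced from subcutaneous tumors of ZR751, a human breast cancer cell line positive for hormone receptors and negative for HER2, grown in female NSG mice, which lack a working adaptive immune system. There were 13 mice, and each gave 2 libraries, A and B, so the table holds 26 libraries; at which step A and B were divided is not given in the sources used here. Vehicle tumors (5 mice) were taken after 3 days of vehicle; the treatment label of these samples reads DMSO and the design text says vehicle. Sensitive tumors (3 mice) were taken after 3 days of atirmociclib (PF-07220060), an inhibitor of the cell cycle kinase CDK4, given by mouth at 60 mg/kg 2 times a day, 7 hours apart. Resistant tumors (5 mice) were taken after 84 to 91 days of the same dose, in a separate study; their treatment time label reads 2040 hours. Tumors were 150 mm3 when dosing began and were collected 3 hours after the last dose, and the batch label is 1 for every sample.

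The deposited table gives TPM for each library, in which a gene's share of the transcripts is scaled to a fixed total, and TPM is the unit the authors made. The sums per library were 999850 to 999889. The submitters' processing notes name FastQC, STAR, HTSeq and RSEM and the genome builds GRCh38 and GRCm38, without versions or roles. How mouse reads were set aside is not given in the sources used here. The table holds TPM and no read counts, so the depth per library is unknown, and no counting interval or lower limit of detection is given. Between 16914 and 17662 genes per library were above 0, and between 13212 and 13578 had at least 1 TPM. Of 30332 entries, 30331 name a gene, and the remaining one, with no name and 1.49 to 5.51 TPM per library, was left out. Another 23 entries have a number in place of a symbol, of which 17 were tested. No gene of the mitochondrial genome is in the table.

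The mouse was the replicate. The log2(TPM + 1) values of libraries A and B were averaged, and genes with a mean TPM of at least 1 in at least 3 mice were kept, which left 14079 genes. One limma model with the trend option covered all 13 mice and the 3 comparisons (limma 3.58.1, R 4.3.3). A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested in a comparison, two-sided). Errors of TPM values are SDs over mice, and errors of log2 changes are the SEs from this model. Because median-of-ratios scaling and quantile normalization moved the median change of all genes by more than 0.1 in resistant versus vehicle tumors, as quantile normalization did in sensitive versus vehicle, log2 changes in all 3 comparisons are given relative to that median unless named as fitted; the SE and adjusted p are as fitted. The medians taken off were -0.07 for sensitive versus vehicle, -0.05 for resistant versus sensitive and -0.14 for resistant versus vehicle.

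Gene lists for 34 processes and cell types were fixed before the data were examined, and the 31 with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01. Adjusted p values for lists are over the 31 lists of a comparison. Each test was repeated with a correlation estimated from the residuals, with fry, which tests a list against no change while camera tests it against all other genes, and as an exact two-sided permutation test on the list score, which is the mean log2(TPM + 1) of the members in a mouse. In the fits with robust eBayes and over 26 libraries, the list test used the ranked form of camera on the moderated statistics. The mitochondrial transcripts, endothelial markers and skeletal muscle markers had too few members to test, with 0, 2 and 1 passing the filter. Symbols were matched through RefSeq synonyms where a list and the table used different names. Gene positions are from GENCODE 29 on GRCh38.

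The rule for naming genes was also set before the data were examined. It takes CDK4, CDK6, CCND1, RB1 and MKI67, every tested member of the CDK-cyclin-RB and estrogen receptor lists, up to 4 members of each other list by adjusted p, and in each comparison the 10 largest rises and 10 largest falls. The last group had to reach a mean of 5 TPM in the higher group, with every mouse of one group above every mouse of the other. The rule allows more genes than are named here, and the choice among them was made after the values were seen. Where 5 or fewer members of a called list stood apart from the rest, they are named whether or not the rule takes them, also after the values were seen. Some genes that these rules take are not reported here, though they stay in the fits and in the counts.

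The same model and list tests were tested on simulated data. Genes were drawn independently of each other, and changes of single genes were set only in genes at about 5 TPM or more in vehicle tumors. Recovery was therefore not measured for lower genes, and the list tests were not checked on correlated genes. Changes of 1 log2 unit were recovered for 95.5% of genes in sensitive versus vehicle, 94.0% in resistant versus sensitive and 95.5% in resistant versus vehicle, and changes of 0.5 for 53.7%, 55.2% and 68.7%. Of all calls in those data, 5.71%, 8.33% and 7.37% were for genes with no change set. Alternatives covered the constant added before the log, the filter, median-of-ratios scaling, quantile normalization, fits with the 2 compared groups alone, robust eBayes, weights per mouse, A or B libraries alone, averaging before the log, fits on 26 libraries, a threshold of 1 log2 unit and leaving out each mouse in turn. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.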

Results

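Gene expression was measured by bulk RNA sequencing in ZR751 breast tumors grown in 13 mice: 5 given vehicle, 3 given the CDK4 inhibitor atirmociclib for 3 days (sensitive) and 5 given it for 84 to 91 days (resistant). Each tumor gave 2 libraries, whose log2 values correlated across genes at 0.989 to 0.994 within a mouse; genes are not independent replicates. Whether the 2 are separate RNA preparations, separate libraries of 1 preparation or sequencing repeats is not given in the sources used here, so the agreement cannot be assigned to any of these steps. All 26 libraries were closest to the other library of their own mouse. The values are TPM, so the depth of a library is unknown. The first principal component held 45.7% of the variance and the second 19.4%. The resistant tumors came from a separate study, of which no vehicle mice are among these samples. Treatment length, study and resistance therefore cannot be told apart in any comparison with the resistant tumors.

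Sensitive and vehicle tumors were compared to see what 3 days of CDK4 inhibition did to tumors that had not yet become resistant. All 37 G2/M genes and 39 of 40 S-phase genes were lower in the treated tumors, while 10 of 25 estrogen receptor targets were higher. With an estimated correlation none of these 3 lists was called (adjusted p = 0.160, 0.324 and 0.324). The estimates were 0.766, 0.802 and 0.358. Members that move together widen the error of this test, so a missing call in it does not show that a list was unchanged. MKI67, which encodes the proliferation marker Ki-67, had a mean of 45.8 ± 8.07 TPM (SD, n = 5) in vehicle tumors and 1.36 ± 0.550 TPM (SD, n = 3) in sensitive tumors. PLK1, a kinase that drives mitosis, went from 72.2 ± 14.9 TPM (SD, n = 5) to 2.49 ± 0.875 TPM (SD, n = 3). CCND1, the gene of cyclin D1, the partner of CDK4, rose from 263 ± 34.6 TPM (SD, n = 5) to 420 ± 51.2 TPM (SD, n = 3). For each of these 3 genes, every sensitive mouse lay on the same side of every vehicle mouse.

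CDK4, the target of the drug (GRCh38 chromosome 12, 57747727 to 57756013), had 289 ± 23.0 TPM (SD, n = 5) in vehicle and 264 ± 13.6 TPM (SD, n = 3) in sensitive tumors and was not called (log2 change -0.06 ± 0.07, adjusted p = 0.217). Its relative CDK6 had at most 0.395 TPM in any mouse and was not tested. CCND1 (chromosome 11, 69641087 to 69654474) rose by 0.75 ± 0.14 (adjusted p = 0.00621). In the CDK-cyclin-RB list, 10 of 23 genes fell and 2 rose; adjusted over the list alone, 11 fell and 2 rose. The median change of the list was -0.26 (adjusted p = 0.00320; adjusted p = 0.324 with an estimated correlation). CDKN2C, an inhibitor of CDK4 and CDK6, fell by 2.40 ± 0.13 (adjusted p = 1.97e-08). CCNE2 and CCNE1, the E-type cyclins that activate CDK2, changed by -2.50 and -1.62, and CDC25A, the phosphatase that activates CDK2, by -2.28. RB1, the retinoblastoma gene, changed by -0.41 ± 0.10 (adjusted p = 0.00458). The other rise was MYC, a growth-promoting transcription factor, at 0.63 ± 0.14 (adjusted p = 0.0142). This call ended without mouse 6-5 (adjusted p = 0.0911) or mouse 6-6 (adjusted p = 0.0718), and over all alternatives its adjusted p ranged from 2.67e-04 to 0.0911. CDKN1A, the gene of the CDK inhibitor p21, was not called, at 82.5 ± 32.3 TPM (SD, n = 5) and 43.3 ± 11.7 TPM (SD, n = 3), except without mouse 1-5 (adjusted p = 0.00744), with weights per mouse or in the fits on 26 libraries.

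All 37 G2/M and mitosis genes fell, over all genes tested and adjusted over the list alone, with a median change of -3.51 (adjusted p = 9.48e-58; adjusted p = 0.160 with an estimated correlation). MKI67 (chromosome 10, 128096659 to 128126385) fell by 4.24 ± 0.31 (adjusted p = 3.39e-07), and PLK1 (chromosome 16, 23677656 to 23690367) by 4.33 ± 0.20 (adjusted p = 7.02e-09). PTTG1, the securin that holds back the separation of sister chromatids, UBE2C, a ubiquitin ligase partner of the anaphase-promoting complex, and NUSAP1, a spindle protein, changed by -4.57, -4.56 and -4.30. CENPA, the histone of centromeres, and CCNB1, cyclin B1, changed by -3.81 and -2.80. Of 40 S-phase and E2F target genes, 39 fell, and adjusted over the list alone 40 fell; the exception over all genes was POLA1, the catalytic subunit of DNA polymerase alpha (adjusted p = 0.0901), which was called without mouse 9-8 (adjusted p = 0.0130), with weights per mouse or the 2 compared groups alone and in the fits on 26 libraries. The median change of this list was -1.54 (adjusted p = 1.11e-26; adjusted p = 0.324 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, changed by -4.11, CCNA2, cyclin A2, by -3.60 and MYBL2, a transcription factor of the cell cycle, by -2.64.

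Of 25 estrogen receptor targets, 10 rose and none fell; adjusted over the list alone, 13 rose. The median change was 0.92 (adjusted p = 2.36e-08; adjusted p = 0.324 with an estimated correlation). The list score of sensitive mouse 6-4 (5.92) was below that of vehicle mouse 1-6 (6.22). TFF3, a secreted trefoil peptide, rose from 296 ± 110 TPM (SD, n = 5) to 923 ± 384 TPM (SD, n = 3), a change of 1.69 ± 0.28 (adjusted p = 0.00146). RERG, an estrogen-regulated small GTPase, rose by 0.94 ± 0.18 (adjusted p = 0.00506). The progesterone receptor gene PGR (1.63) and the receptor cofactor gene GREB1 (1.01) were called, and their calls ended without mouse 6-5 (adjusted p = 0.0992 and 0.115) or mouse 6-6 (adjusted p = 0.0675 and 0.0890). Over all alternatives the adjusted p ranged from 1.20e-04 to 0.0992 for PGR and from 5.90e-04 to 0.115 for GREB1. ESR1, the gene of the receptor itself, was not called, at 113 ± 59.0 TPM (SD, n = 5) and 104 ± 26.8 TPM (SD, n = 3).

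Ribosomal protein genes rose in 11 of 25 cases and in 20 adjusted over the list alone, with a median change of 0.35 (adjusted p = 1.10e-13; adjusted p = 0.324 with an estimated correlation). RPL13 rose by 0.42 ± 0.07 (adjusted p = 0.00361). After quantile normalization the median change of these genes was 0.03, the same as that of all genes, and the call ended (adjusted p = 0.161; range over alternatives 6.32e-16 to 0.324). Of 20 hypoxia and glycolysis genes, 6 rose and none fell; adjusted over the list alone, 8 rose. Their median change was 0.61 (adjusted p = 2.19e-07; adjusted p = 0.324 with an estimated correlation), and fry did not call them (adjusted p = 0.0641; range over alternatives 2.88e-15 to 0.324). The list score was higher in mice 6-5 (5.28) and 6-6 (5.52), while that of mouse 6-4 (4.53) was within the vehicle range (4.53 to 4.67). VEGFA, the angiogenic growth factor, was called at 0.86 ± 0.20 (adjusted p = 0.0163), but not without mouse 6-5 (adjusted p = 0.0811) or mouse 6-6 (adjusted p = 0.108; range over alternatives 4.75e-04 to 0.108).

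Smaller falls were seen in 4 further lists. Of 22 cholesterol synthesis genes, 7 fell and none rose, and adjusted over the list alone 10 fell (median -0.18, adjusted p = 0.00965; adjusted p = 0.594 with an estimated correlation). EBP, a sterol isomerase, changed by -0.80 ± 0.14 (adjusted p = 8.54e-04). The list was not called without vehicle mouse 1-6 (adjusted p = 0.110) or with robust eBayes (adjusted p = 0.0618; range over alternatives 0.00131 to 0.594). Of 20 p53 targets, 7 fell and none rose, and adjusted over the list alone 9 fell (median -0.22, adjusted p = 0.00796; adjusted p = 0.507 with an estimated correlation). POLH, a DNA polymerase that copies past damage, changed by -0.61, and the death receptor gene FAS by -0.88. Of 23 nuclear genes of oxidative phosphorylation, 9 fell and none rose, and adjusted over the list alone 12 fell (median -0.11, adjusted p = 0.00561; adjusted p = 0.507 with an estimated correlation). This call ended with median-of-ratios scaling (adjusted p = 0.113) and quantile normalization (adjusted p = 0.258; range over alternatives 7.16e-05 to 0.507). Of 11 replication-dependent histone genes, 4 fell and none rose, and adjusted over the list alone 6 fell (median -0.28, adjusted p = 0.0352; adjusted p = 0.562 with an estimated correlation). They were HIST1H1C, HIST1H2AE, HIST1H2BC and HIST1H2BG. The last 3 were not called without mouse 6-5 (adjusted p = 0.136, 0.209 and 0.0634), HIST1H2BC not without 1-2, 1-4, 1-9 or 6-6 either (adjusted p = 0.0712, 0.0626, 0.0712 and 0.0792), and HIST1H1C not with quantile normalization (adjusted p = 0.0580). That list was not called without mouse 1-4, 1-5 or 6-5 (adjusted p = 0.0591, 0.0812 and 0.0708), nor with a filter at a mean of 5 TPM, robust eBayes, B libraries alone or the fits on 26 libraries (range over alternatives 0.00611 to 0.562).

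Among other genes, CHI3L1, which encodes a secreted chitinase-like protein, rose from 2.04 ± 1.77 TPM (SD, n = 5) to 33.1 ± 22.2 TPM (SD, n = 3). TIMP3, an inhibitor of matrix metalloproteinases, rose by 2.39 ± 0.35 (adjusted p = 5.13e-04), MUC2, a secreted mucin, by 2.21 and BASP1, a protein of the inner cell membrane, by 2.15. LMNB1, a protein of the nuclear lamina, changed by -2.16, PHGDH, the first enzyme of serine synthesis, by -1.18 and NMU, a neuropeptide gene, by -4.03. B2M, the light chain of MHC class I, changed by -0.58 and the immunoproteasome subunit gene PSMB8 by -0.45, in a list of 14 antigen presentation genes that was not called (CD74 higher; B2M, PSMB8, PSMB9 and TAP1 lower, also adjusted over the list alone). Without mouse 6-5 or 6-6 neither CD74 (adjusted p = 0.0889 and 0.129) nor TAP1 (adjusted p = 0.136 and 0.162) was called, nor was TAP1 without mouse 1-9 (adjusted p = 0.0538) or with either scaling, nor PSMB9 in B libraries alone (adjusted p = 0.0683).

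For every called gene given with its change or TPM above, all 3 sensitive mice lay on one side of all 5 vehicle mice. In all, 445 genes were higher and 1767 lower in sensitive tumors. Groups did not overlap for 21.8% of genes, against 3.57% by chance. The counts were 794 and 1052 with median-of-ratios scaling and 938 and 989 with quantile normalization. They were 100 and 801 without mouse 6-5, 111 and 963 without mouse 6-6, and 288 higher without mouse 1-9. With an estimated correlation 0 of the 31 lists passed (3 had an unadjusted p under 0.05), against 10 by camera and 11 by fry. With 56 ways to assign the mice, the exact permutation test on list scores cannot go below 0.0179 unadjusted, and the smallest adjusted p was 0.0923.

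**Figure D1:**
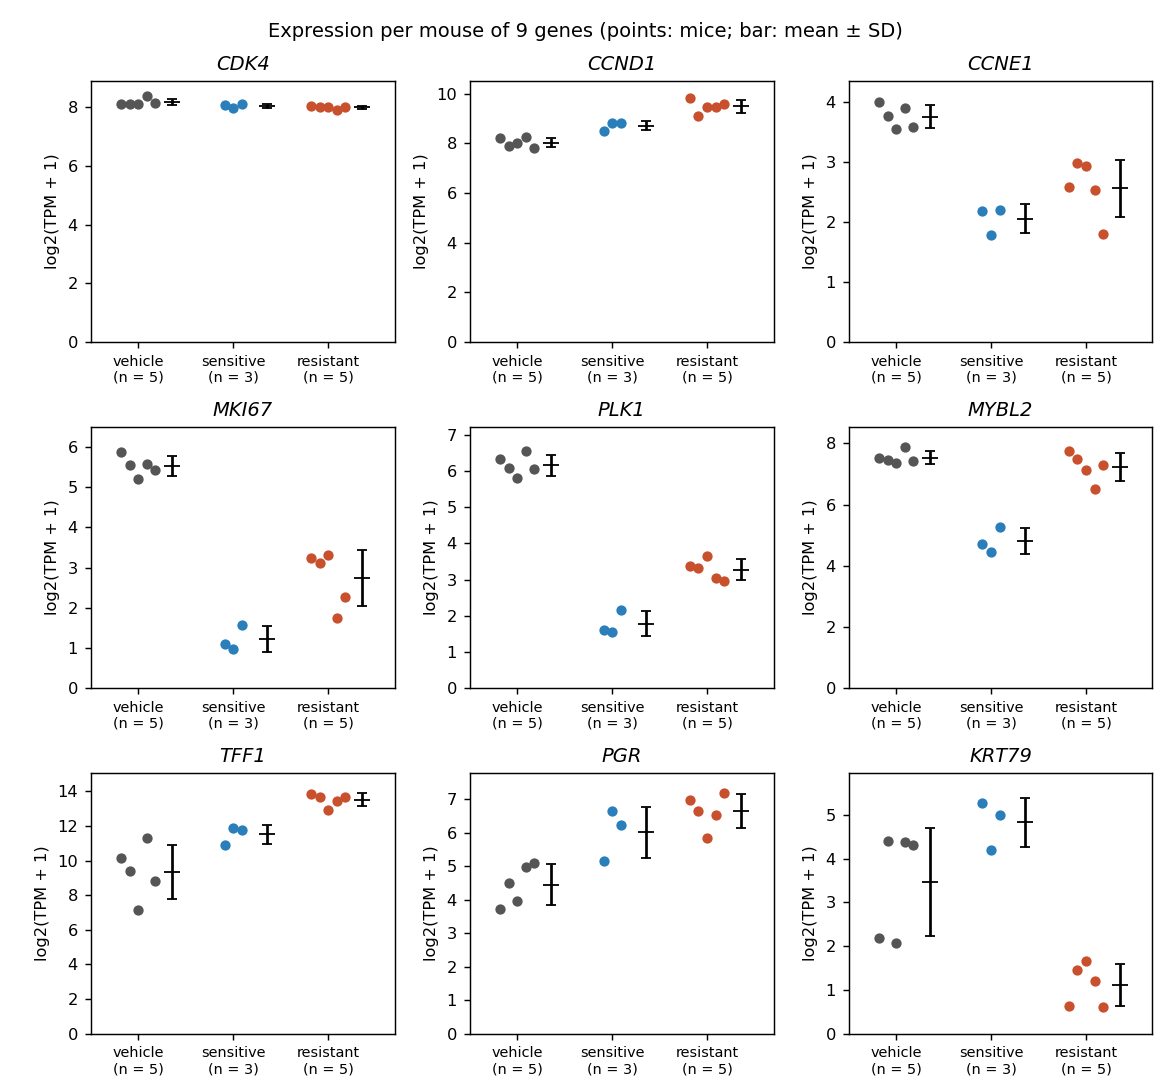
Expression of 9 genes in each mouse, as log2(TPM + 1), in the vehicle (5 mice), sensitive (3 mice) and resistant (5 mice) groups; points are mice and bars show the mean ± SD. MKI67 was 45.8 TPM in vehicle, 1.36 in sensitive and 6.24 in resistant tumors, while TFF1 was 988, 3078 and 12018 TPM.

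Resistant and sensitive tumors were compared to see how tumors after 84 to 91 days of the drug differed from those in their first 3 days of it. Of the genes of mitosis 35 of 37 were higher in the resistant tumors, as were 25 of 40 S-phase genes, 11 of 25 estrogen receptor targets and 10 of 17 immediate early genes; with an estimated correlation none of these lists was called (adjusted p = 0.384 to 0.451). MYBL2 had 28.0 ± 8.81 TPM (SD, n = 3) in sensitive and 155 ± 45.6 TPM (SD, n = 5) in resistant tumors. CTSD, the estrogen-regulated protease cathepsin D, went from 490 ± 75.7 TPM (SD, n = 3) to 2112 ± 810 TPM (SD, n = 5). The largest falls included CES1, a carboxylesterase, KRT79, a keratin, and AWAT2, an enzyme of wax ester synthesis. For all 5 of these genes, every resistant mouse lay on one side of every sensitive mouse.

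Of the 37 G2/M and mitosis genes, 35 rose and none fell, and adjusted over the list alone 36 rose (median 1.33, adjusted p = 1.40e-25; adjusted p = 0.384 with an estimated correlation). The members not called were CENPE and KIF23, which encode kinesins of mitosis; KIF23 was called without mouse 9-8 or 9-9 (adjusted p = 0.0373 and 0.0246), with weights per mouse and in the fits on 26 libraries. MKI67 rose by 1.56 ± 0.31 (adjusted p = 0.00515), PLK1 by 1.55 ± 0.20 (adjusted p = 3.98e-04) and PTTG1 by 1.86 ± 0.23 (adjusted p = 3.35e-04). Of the 40 S-phase and E2F targets, 25 rose and none fell, and adjusted over the list alone 34 rose (median 0.87, adjusted p = 2.11e-15; adjusted p = 0.451 with an estimated correlation). MYBL2 (chromosome 20, 43667019 to 43716496) rose by 2.46 ± 0.23 (adjusted p = 6.22e-05). RRM2 rose by 2.12, TK1, a thymidine kinase made in S phase, by 1.97 and TYMS, thymidylate synthase, by 1.81.

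The CDK-cyclin-RB list was not called (5 higher and 4 lower of 23, also adjusted over the list alone; adjusted p = 0.203). CCND1 rose from 420 ± 51.2 TPM (SD, n = 3) to 727 ± 129 TPM (SD, n = 5), a change of 0.82 ± 0.14 (adjusted p = 0.00291). CDK2 rose by 0.57 ± 0.11 (adjusted p = 0.00564), and SKP2, which marks the CDK inhibitor p27 for degradation, fell by 0.62 ± 0.15 (adjusted p = 0.00749). CCNE1 was not called, at 3.19 ± 0.651 TPM (SD, n = 3) and 5.13 ± 1.77 TPM (SD, n = 5), except without mouse 9-9 (adjusted p = 0.0123). CDK4 and RB1 were not called (adjusted p = 0.671 and 0.961).

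Of the 25 estrogen receptor targets, 11 rose and none fell, and adjusted over the list alone 17 rose (median 1.09, adjusted p = 1.83e-09; adjusted p = 0.384 with an estimated correlation). CTSD rose by 2.09 ± 0.23 (adjusted p = 1.62e-04), AREG, which encodes the EGF receptor ligand amphiregulin, by 2.36 ± 0.29 (adjusted p = 3.41e-04) and TFF3 by 1.43 ± 0.28 (adjusted p = 0.00471). Of 17 immediate early and AP-1 genes, 10 rose and none fell, and adjusted over the list alone 13 rose (median 0.85, adjusted p = 2.46e-07; adjusted p = 0.384 with an estimated correlation). FOSB, a subunit of AP-1, rose from 0.918 ± 0.203 TPM (SD, n = 3) to 75.8 ± 94.9 TPM (SD, n = 5), with resistant mice from 7.26 TPM (9-9) to 231 TPM (9-8). FOS, another subunit, rose by 3.42, and the transcription factor gene EGR1 by 2.95. Resistant mice varied widely in both, with 55.7 ± 51.4 TPM for FOS and 43.2 ± 37.7 TPM for EGR1 (SD, n = 5). The SD of the list score was 0.661 in resistant (n = 5) and 0.0682 in sensitive mice (n = 3).

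Interferon response genes rose in 6 of 19 cases, with none lower, and in 10 adjusted over the list alone (median 0.57, adjusted p = 8.40e-05; adjusted p = 0.451 with an estimated correlation). IFI6, an interferon-induced membrane protein, rose by 2.42 ± 0.51 (adjusted p = 0.00637) and SAMD9 by 0.92. Mouse 9-7 stood highest, with IFI6 at 208 TPM (other resistant mice 23.3 to 57.9) and a list score of 4.01 (3.01 to 3.21). Without it the fitted median of the list went from 0.53 to 0.34 (adjusted p = 2.75e-04; range over alternatives 6.18e-06 to 0.451). Antigen presentation genes rose in 4 of 14 cases, with none lower; adjusted over the list alone, 7 rose and 1 fell (median 0.28, adjusted p = 0.00170; adjusted p = 0.384 with an estimated correlation). B2M rose from 199 ± 16.1 TPM (SD, n = 3) to 399 ± 59.3 TPM (SD, n = 5). PSMB8 rose by 0.67, and HLA-C and HLA-F were the other rises. Lysosome and autophagy genes rose in 6 of 25 cases, the same number as adjusted over the list alone (median 0.28, adjusted p = 1.71e-05; adjusted p = 0.430 with an estimated correlation). They included NPC2, which moves cholesterol out of lysosomes (0.72), and WIPI1, a protein of forming autophagosomes (1.30). Of 20 p53 targets, 6 rose and none fell, and adjusted over the list alone 7 rose (median 0.41, adjusted p = 0.00237; adjusted p = 0.451 with an estimated correlation), among them the DNA repair gene DDB2 (0.81). Of 12 NF-kB response genes, 3 rose and 1 fell, and adjusted over the list alone 5 rose and 1 fell (median 0.53, adjusted p = 0.0318; adjusted p = 0.451 with an estimated correlation). The death ligand gene TNFSF10 rose by 1.80 and the adhesion gene ICAM1 by 1.12, as did the inhibitor gene NFKBIA, while TRAF1, a signalling adaptor, fell. The calls of NFKBIA and TRAF1 ended without mouse 6-4, 6-5 or 6-6, and without 9-7 and 9-3 in turn (without 6-5, adjusted p = 0.112 and 0.0651). That list was not called without mouse 6-5 (adjusted p = 0.0756) or 9-7 (adjusted p = 0.0516), or with median-of-ratios scaling (adjusted p = 0.0586), a filter at a mean of 5 TPM, weights per mouse or the 2 compared groups alone (range over alternatives 0.00535 to 0.451).

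Ribosomal protein genes fell in 16 of 25 cases and in 19 adjusted over the list alone (median -0.23, adjusted p = 2.46e-07; adjusted p = 0.451 with an estimated correlation), with RPL13 at -0.44 ± 0.07 (adjusted p = 6.02e-04). Of 23 MYC targets and ribosome biogenesis genes, 5 fell and none rose, and adjusted over the list alone 7 fell (median -0.13, adjusted p = 0.0129; adjusted p = 0.451 with an estimated correlation). POLR1A, the large subunit of RNA polymerase I, changed by -0.52, and the others that fell were BOP1, CAD, FBL and NPM1. The calls of these 4 ended without mouse 6-5 or 6-6 and with median-of-ratios scaling, that of BOP1 also without 9-7, that of NPM1 without any of 7 other mice and that of CAD without any of 9 (adjusted p up to 0.121, 0.206, 0.103 and 0.202 over alternatives). That list was not called without mouse 6-6 (adjusted p = 0.0635; range over alternatives 0.00188 to 0.451). Of 20 hypoxia and glycolysis genes, 7 fell and 2 rose, and adjusted over the list alone 11 fell and 2 rose (median -0.53, adjusted p = 0.0129; adjusted p = 0.597 with an estimated correlation). EGLN3, an oxygen sensor, changed by -1.39 and the hexokinase gene HK2 by -0.65, while the glucose transporter gene SLC2A1 rose by 0.89 and the transcription factor gene BHLHE40 was the other rise, a call that ended without mouse 6-4, 6-5, 6-6, 9-6 or 9-9 (adjusted p up to 0.131 over alternatives). The call ended without mouse 6-5 (adjusted p = 0.0814) or 6-6 (adjusted p = 0.219), and fry did not call the list (adjusted p = 0.0799; range over alternatives 2.75e-08 to 0.597).

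Of 12 basal and stem-like keratin genes, 7 fell and 2 rose, and adjusted over the list alone 8 fell and 2 rose (median -1.23, adjusted p = 0.0339; adjusted p = 0.451 with an estimated correlation). KRT14, a keratin of basal epithelium, fell from 11.5 ± 5.55 TPM (SD, n = 3) to 0.421 ± 0.287 TPM (SD, n = 5), and PROM1, the gene of the surface marker CD133, changed by -1.71. The genes that rose were ITGA6, an integrin of basal cells (1.97), and CD44, a hyaluronan receptor, whose call ended without mouse 6-5, 6-6 or 9-6 (adjusted p up to 0.0987 over alternatives). The call ended without mouse 6-6, 9-8 or 9-9 (adjusted p = 0.0593, 0.0558 and 0.0689) and with weights per mouse (adjusted p = 0.0547). It also ended with no filter (adjusted p = 0.113) and with a filter at a mean of 5 TPM (adjusted p = 0.879; range over alternatives 9.28e-04 to 0.879), where the fitted median went from -1.28 to -0.13 and -0.09. CES1 changed by -3.74 ± 0.61 (adjusted p = 0.00133), and AWAT2 by -3.67 ± 0.52 (adjusted p = 5.91e-04). KRT79, a keratin of hair follicle and sebaceous duct (chromosome 12, 52821410 to 52834295), went from 28.7 ± 10.4 TPM (SD, n = 3) to 1.25 ± 0.721 TPM (SD, n = 5). CASP14, a caspase of keratinizing cells, changed by -2.96. S100A8, a calcium-binding protein of neutrophils and stressed epithelium, changed by -2.57. The leukocyte gene PTPRC had at most 0.015 TPM in any mouse. Leukocytes of the host would be mouse cells and the table holds human symbols, so this value cannot tell whether they were present.

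The largest rises included RAB31, a small GTPase of vesicle traffic, from 8.66 ± 3.48 TPM (SD, n = 3) to 153 ± 78.2 TPM (SD, n = 5). CLIC6, a chloride channel gene, rose by 3.83, TFF2, a trefoil peptide, by 3.67, MGP, an inhibitor of calcification, by 3.17 and FHL2, a LIM-domain cofactor, by 3.00. For every called gene given with its change or TPM in this comparison, all 5 resistant mice lay on one side of all 3 sensitive mice. In all, 1346 genes were higher and 1631 lower in resistant than in sensitive tumors. Groups did not overlap for 30.4% of genes, against 3.57% by chance. The counts were 1759 and 1329 with median-of-ratios scaling and 1464 and 1806 with quantile normalization. They were 673 and 795 without mouse 6-5, and 891 and 695 without mouse 6-4. With an estimated correlation 0 of the 31 lists passed (4 had an unadjusted p under 0.05), against 13 by camera and 14 by fry. The exact permutation test on list scores called 0, with a smallest adjusted p of 0.0615.

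**Figure D2:**
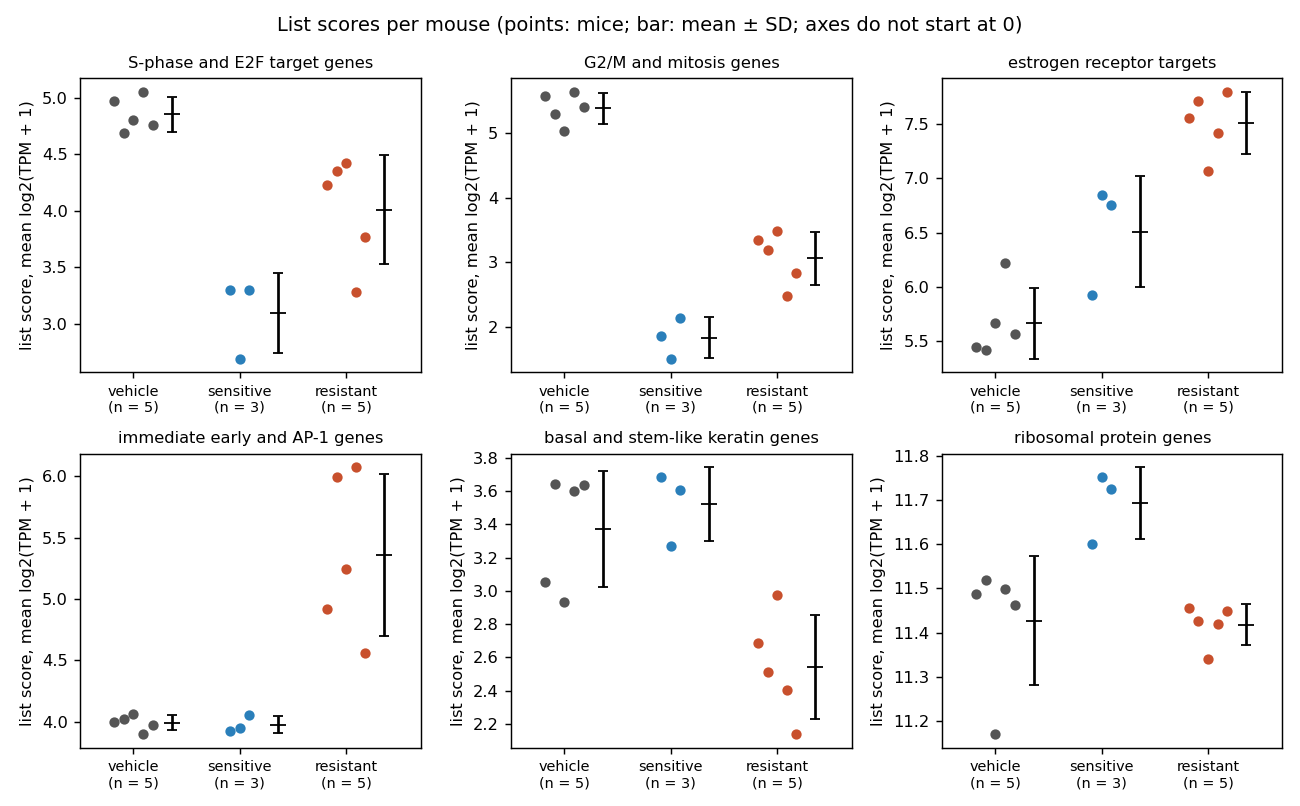
Mean log2(TPM + 1) of the members of 6 gene lists in each mouse, by group, with the mean ± SD; the vertical axes do not start at 0. The score of the 37 G2/M genes averaged 5.39 in vehicle, 1.83 in sensitive and 3.06 in resistant tumors, and that of the 25 estrogen receptor targets 5.66, 6.51 and 7.51.

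Resistant and vehicle tumors were compared to see how far tumors on prolonged treatment stood from untreated ones. Of 25 estrogen receptor targets 23 were higher in the resistant tumors, and all 37 mitosis genes were lower; with an estimated correlation neither list was called (adjusted p = 0.197 and 0.351). TFF1, an estrogen-induced trefoil peptide, had 988 ± 941 TPM (SD, n = 5) in vehicle and 12018 ± 2735 TPM (SD, n = 5) in resistant tumors. PGR went from 22.5 ± 9.38 TPM (SD, n = 5) to 104 ± 33.4 TPM (SD, n = 5). MKI67 went from 45.8 ± 8.07 TPM (SD, n = 5) to 6.24 ± 2.97 TPM (SD, n = 5). For these 3 genes the values of the groups did not overlap.

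Of the 25 estrogen receptor targets, 23 rose and none fell, with the same numbers adjusted over the list alone (median 1.78, adjusted p = 2.24e-20; adjusted p = 0.197 with an estimated correlation). The list score was higher in resistant tumors (exact permutation test, adjusted p = 0.0189). TFF1 (chromosome 21, 42362282 to 42366594) rose by 4.29 ± 0.56 (adjusted p = 8.39e-05), PGR (chromosome 11, 101029624 to 101130524) by 2.32 ± 0.33 (adjusted p = 1.88e-04) and GREB1 by 1.78 ± 0.21 (adjusted p = 6.05e-05). CTSD rose by 2.43 and SIAH2, a ubiquitin ligase, by 1.98. The members not called were ESR1 (adjusted p = 0.871) and RARA, a retinoic acid receptor gene (adjusted p = 0.116), which was called without mouse 9-6 (adjusted p = 0.0462), with median-of-ratios scaling, with weights per mouse and in the fits on 26 libraries.

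All 37 G2/M and mitosis genes fell, also adjusted over the list alone (median -2.11, adjusted p = 4.37e-24; adjusted p = 0.351 with an estimated correlation). PLK1 changed by -2.76 ± 0.17 (adjusted p = 1.10e-07) and KIF20A, a kinesin of cell division, by -2.93 ± 0.18 (adjusted p = 1.09e-07). Of the 40 S-phase and E2F targets, 21 fell and none rose, and adjusted over the list alone 23 fell (median -0.52, adjusted p = 1.76e-04; adjusted p = 0.715 with an estimated correlation). RRM2 changed by -1.98 and CCNA2 by -2.49. MYBL2 was not called, at 185 ± 29.3 TPM (SD, n = 5) and 155 ± 45.6 TPM (SD, n = 5), nor was TK1, at 86.8 ± 9.48 TPM (SD, n = 5) and 68.8 ± 28.0 TPM (SD, n = 5). Of 11 histone genes, 8 fell and none rose, also adjusted over the list alone (median -0.29, adjusted p = 0.0139; adjusted p = 0.594 with an estimated correlation), with HIST1H2BG at -0.70. HIST1H3B, HIST1H2AE and HIST1H1E were not called.

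In the CDK-cyclin-RB list, 14 of 23 genes fell and 1 rose; adjusted over the list alone, 14 fell and 2 rose (median -0.27, adjusted p = 0.0460; adjusted p = 0.594 with an estimated correlation). CCND1 was the gene that rose, by 1.59 ± 0.12 (adjusted p = 2.33e-06). CDKN2C changed by -1.95 ± 0.11 (adjusted p = 5.87e-08), CCNE1 by -1.06 ± 0.19 (adjusted p = 3.28e-04) and RB1 by -0.36 ± 0.08 (adjusted p = 5.16e-04). CDKN2A, the gene of the CDK4 inhibitor p16, changed by -1.01 ± 0.25 (adjusted p = 0.00253). CDK4 had 255 ± 8.89 TPM (SD, n = 5) in resistant tumors and its fitted change was called as a fall (adjusted p = 0.0278). The fitted change includes the shift of all genes (median -0.14), and relative to that median CDK4 changed by only -0.04 ± 0.06. That call ended without mouse 1-6 (adjusted p = 0.0530) or 9-8 (adjusted p = 0.0677) and with median-of-ratios scaling (adjusted p = 0.855), quantile normalization (adjusted p = 0.379) or A libraries alone (adjusted p = 0.104; range over alternatives 0.00388 to 0.855). The list was not called without mouse 1-2, 1-6, 6-4 or 9-9 (adjusted p = 0.0601, 0.113, 0.0513 and 0.0590), nor with a constant of 0.1, a filter at a mean of 5 TPM, weights per mouse or A libraries alone (range over alternatives 9.90e-05 to 0.594).

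Of 17 immediate early and AP-1 genes, 12 rose and none fell, also adjusted over the list alone (median 0.82, adjusted p = 9.48e-08; adjusted p = 0.351 with an estimated correlation). FOSB rose by 4.31 ± 0.67 (adjusted p = 3.28e-04) and FOS by 4.30 ± 0.53 (adjusted p = 5.40e-05), while BTG2, DUSP1, FOSL1, IER2 and KLF6 were not called; DUSP1 was called without mouse 9-9 (adjusted p = 0.0356), DUSP1 and BTG2 in the fits on 26 libraries and BTG2 with median-of-ratios scaling. Of 22 cholesterol synthesis genes, 16 fell and none rose, also adjusted over the list alone (median -0.30, adjusted p = 0.00107; adjusted p = 0.594 with an estimated correlation). SQLE, squalene epoxidase, changed by -0.83 ± 0.11 (adjusted p = 1.75e-05). Of 25 lysosome and autophagy genes, 8 rose and 1 fell, and adjusted over the list alone 7 rose and 1 fell (median 0.27, adjusted p = 5.72e-04; adjusted p = 0.458 with an estimated correlation), with WIPI1 at 1.59; the gene that fell was CTSB, a lysosomal protease. That fall is a fitted change, which includes the shift of all genes (median -0.14). It was no longer called with quantile normalization or without any of 7 mice (1-4, 1-5, 1-6, 1-9, 9-3, 9-6 or 9-8). Nor was it called with median-of-ratios scaling, where its sign turned (adjusted p = 0.947, range over alternatives 0.00567 to 0.947).

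Of 26 growth factor receptor and PI3K-MAPK feedback genes, 10 rose and 8 fell, also adjusted over the list alone (median 0.31, adjusted p = 0.0123; adjusted p = 0.198 with an estimated correlation). IGF1R, the receptor of insulin-like growth factor 1, rose by 1.29 ± 0.13 (adjusted p = 1.53e-05) and FGFR3 by 0.94, while FGFR4 changed by -1.66 ± 0.17 (adjusted p = 5.00e-06) and FGFR1 by -0.65. The list call ended with median-of-ratios scaling (adjusted p = 0.115) and quantile normalization (adjusted p = 0.0633), and with a filter at a mean of 5 TPM (adjusted p = 0.0600; range over alternatives 0.00650 to 0.198), where the fitted median went from 0.17 to -0.11. Interferon response genes rose in 6 of 19 cases, also adjusted over the list alone, with none lower (median 0.40, adjusted p = 0.0123; adjusted p = 0.618 with an estimated correlation). This call ended without mouse 9-7 (adjusted p = 0.0512), where the fitted median went from 0.26 to 0.02, and with a filter at a mean of 5 TPM (adjusted p = 0.0910), where it was 0.01. Fry did not call the list (adjusted p = 0.231; range over alternatives 0.00299 to 0.618). Antigen presentation genes rose in 4 of 14 cases and fell in 2; adjusted over the list alone, 5 rose and 4 fell (median 0.27, adjusted p = 0.0255; adjusted p = 0.406 with an estimated correlation). HLA-F, an MHC class I gene, rose by 1.19, B2M and CD74 were among the others that rose, and PSMB9 and TAP1 fell. CD74 was not called without mouse 1-2, 1-4, 1-5, 9-3, 9-6 or 9-9 (adjusted p up to 0.0912 over alternatives), nor TAP1 with either scaling (up to 0.111). The call ended without mouse 9-8 (adjusted p = 0.0526) and in the fits on 26 libraries (range over alternatives 0.0122 to 0.406). NF-kB response genes rose in 5 of 12 cases and fell in 2, also adjusted over the list alone (median 0.48, adjusted p = 0.0175; adjusted p = 0.406 with an estimated correlation). ICAM1, NFKBIA, RELB, TNFAIP3 and TNFSF10 rose, NFKB1 and TRAF1 fell; the call of RELB ended without mouse 1-4, 1-5, 1-9, 9-3, 9-7 or 9-8 (adjusted p up to 0.106 over alternatives), that of NFKB1 with quantile normalization and that of TRAF1 in A libraries alone, and the list was not called with median-of-ratios scaling (adjusted p = 0.0598) or a filter at a mean of 5 TPM (adjusted p = 0.0707; range over alternatives 0.00615 to 0.406). Of 19 unfolded protein and integrated stress response genes, 4 rose and 2 fell; adjusted over the list alone, 3 rose and 2 fell (median 0.22, adjusted p = 0.0255; adjusted p = 0.406 with an estimated correlation). The genes that fell, PHGDH and PSAT1, encode enzymes of serine synthesis, and those that rose were DDIT3, EDEM1, HSPA5 and MANF. The calls of PSAT1 (without 1-2, 1-4, 1-6, 9-6 or 9-9), HSPA5 (without 1-2, 1-4, 1-9, 9-3, 9-6, 9-8 or 9-9) and MANF (without 1-4, 1-9, 9-3, 9-7 or 9-8) each ended, with adjusted p up to 0.0692, 0.101 and 0.0805 over alternatives. The call ended without mouse 9-3 (adjusted p = 0.0505), with median-of-ratios scaling (adjusted p = 0.0541) or robust eBayes and in the fits on 26 libraries, and neither fry (adjusted p = 0.196; range over alternatives 0.00937 to 0.406) nor the exact permutation test on the list score (adjusted p = 0.400) called the list.

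Among other genes, SEMA3B, a secreted semaphorin, rose from 4.28 ± 2.97 TPM (SD, n = 5) to 103 ± 32.3 TPM (SD, n = 5). TIMP3 rose by 4.37 ± 0.30 (adjusted p = 4.60e-07), TFF2 by 4.37 and SERPINA6, a corticosteroid-binding globulin, by 4.10. PVALB, a calcium-binding protein, went from 65.4 ± 17.8 TPM (SD, n = 5) to 2.79 ± 1.05 TPM (SD, n = 5). BAMBI, a decoy receptor of the TGF-beta family, changed by -2.83 and SOX2, a stem cell transcription factor, by -2.19. GATA3, a transcription factor of luminal cells, changed by -0.52. For every called gene given with its change or TPM in this comparison other than CDKN2A and SOX2, the groups did not overlap. In all, 1624 genes were higher and 4570 lower. Groups did not overlap for 27.3% of genes, against 0.794% by chance. The counts were 2622 and 2363 with median-of-ratios scaling and 2333 and 2773 with quantile normalization. With an estimated correlation 0 of the 31 lists passed (4 had an unadjusted p under 0.05), against 13 by camera, 17 by fry and 17 by the exact permutation test on list scores, which held 12 of camera's 13. A list's median, mean and test differed in sign for 7, 4 and 11 lists in the 3 comparisons, none of them called by camera.

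The 3-day changes were followed into the resistant tumors to see which persisted. Many genes lowered at 3 days, among them CDKN2C, CCNE1 and PLK1, were also below vehicle in resistant tumors, and others, such as MYBL2 and FBLN1, an extracellular matrix protein, were higher in resistant than in sensitive tumors and not called against vehicle. FBLN1 had 38.1 ± 8.94 TPM (SD, n = 5) in vehicle, 8.91 ± 1.07 TPM (SD, n = 3) in sensitive and 34.3 ± 9.28 TPM (SD, n = 5) in resistant tumors. TFF3 and CCND1 rose at 3 days and were higher again in resistant than in sensitive tumors. Of 1767 genes lower at 3 days, 1245 (70.5%) were also lower in resistant than in vehicle tumors, and 493 (27.9%) were higher in resistant than in sensitive tumors; 225 were in both sets and 254 in neither. Independent lists of these sizes would share 574 and 169 genes. Of 445 genes higher at 3 days, 258 (58.0%) were also higher in resistant than in vehicle tumors, and 107 (24.0%) were lower in resistant than in sensitive tumors; 2 (CGNL1 and GAS5) were in both sets and 82 in neither. Without mouse 6-5 neither of the 2 was called in resistant versus sensitive tumors (adjusted p = 0.172 and 0.113). Independent lists would share 51.3 and 51.6. With median-of-ratios scaling 620 genes were lower and 479 higher in both comparisons with vehicle, and with quantile normalization 632 and 522.

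The comparisons share groups, so overlaps arise in part from the shared mice. Across genes, which are not independent replicates, the 3-day changes and the resistant versus vehicle changes correlated at 0.619, against 0.433 in 100 simulated tables without any change. The 3-day changes and the resistant versus sensitive changes correlated at -0.296, against -0.625 in the simulated tables. Tables without any change hold only noise, so their correlation follows from the group sizes and is no baseline for data with changes. The covariance, which is not divided by the spread of the changes, was 0.152 for the first pair, against 0.0110 simulated. For the second pair it was -0.0598, against -0.0183 simulated, so both were further from 0 than the shared mice alone gave. When the vehicle mice were divided, 2 for one comparison and 3 for the other, the correlation averaged 0.526 over 20 fits, and 59.1% of genes lower at 3 days were lower in both (range 45.3% to 78.3%), 707 genes on average. Of genes higher at 3 days 40.8% were higher in both (range 23.4% to 78.1%), 102 on average. When the sensitive mice were divided, 1 and 2, a test chosen after the values were seen, the correlation with the resistant versus sensitive changes averaged -0.214 over 6 fits (range -0.397 to 0.0199). On average 124 genes (10 to 182) were then lower at 3 days and higher in resistant than in sensitive tumors, and 8.33 (4 to 17) were higher and then lower; a group of 1 mouse is assumed to vary like the others. Without mouse 6-5, 655 genes were lower in both and 65 higher in both, and 175 were lower at 3 days and then higher in resistant than in sensitive tumors. Without mouse 6-6, 23 genes were higher at 3 days and then lower.

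**Figure D3:**
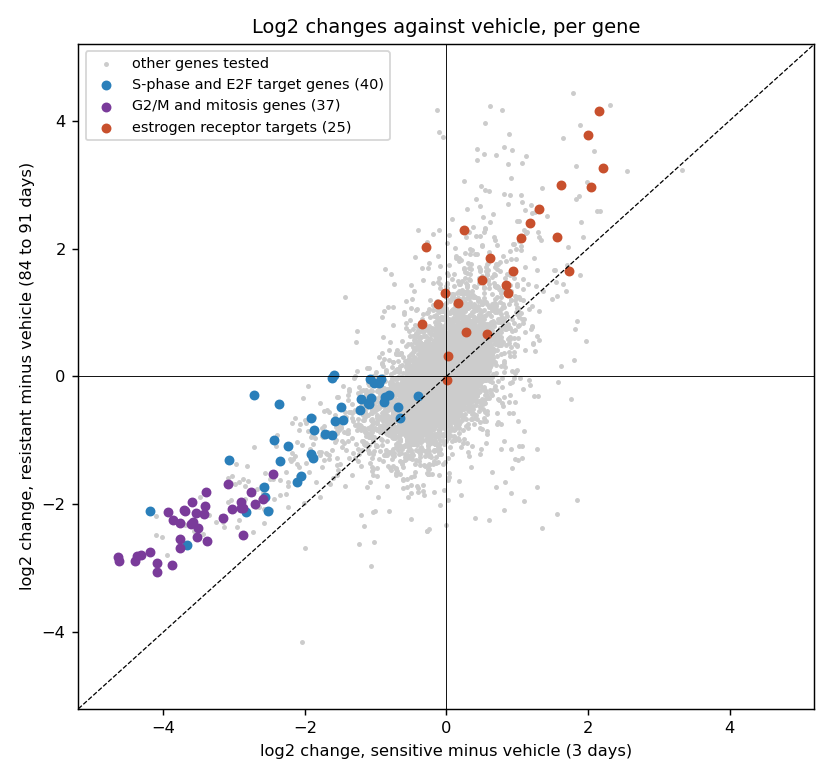
Log2 change in TPM + 1 of each tested gene after 3 days (horizontal, sensitive minus vehicle) against that after 84 to 91 days (vertical, resistant minus vehicle), as fitted and not relative to the median; 40 S-phase, 37 G2/M and 25 estrogen receptor target genes are colored and the dashed line marks equal changes. All 37 G2/M genes lie below 0 on both axes and the estrogen receptor targets lie mostly above 0 on both.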

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

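Of the tests on the 3 patterns, those chosen only after the result was seen are the count of estrogen receptor targets between resistant and sensitive tumors, the percent of the 3-day fall remaining, the 3 markers of outer epidermis (chosen from a longer list of skin markers) and the 3 statements on the difference between the studies.

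Estrogen receptor targets were higher in resistant than in vehicle tumors, with 23 of 25 called. If a few abundant transcripts had set the scale of the TPM, rescaling should end the calls. After median-of-ratios scaling 24 were called higher, but that scaling could not have ended them. The 10 highest genes held 9.45% to 11.2% of the TPM in resistant and 6.72% to 8.37% in vehicle libraries. The rescaling raised the median change of all genes from -0.14 to 0.00525. The shift it removed was downward in resistant tumors, opposite to the rise of the targets. If a lower share of dividing cells were the whole cause, the targets should not rise where division genes rise. Between sensitive and resistant tumors the targets called higher exceeded those called lower by 11 while 35 of 37 G2/M genes rose. That comparison uses the same resistant mice and is confounded with study, so it cannot decide this. At 3 days the targets rose (median 0.92) while the G2/M genes fell (median -3.51). In resistant tumors the G2/M genes were still below vehicle (median -2.11), so a part played by fewer dividing cells stays open. A difference between the 2 studies cannot be told apart from treatment length or resistance, since 0 vehicle mice of the second study are among these samples. An effect of prolonged CDK4 inhibition or of resistance on these genes may stand behind the pattern and was not tested.

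In resistant tumors S-phase genes were nearer to the vehicle level than G2/M genes: the S-phase minus G2/M list score was 1.48 higher than in vehicle tumors (exact permutation p = 0.00794, the smallest that 5 mice against 5 can give), 1.79 higher in sensitive than in vehicle tumors and changed by -0.31 from sensitive to resistant tumors (exact permutation p = 0.0357). With a constant of 0.1 before the log the gap was 1.54, which argues against the constant as its cause. Among members that fell by 1.5 to 3 at 3 days (20 S-phase and 8 G2/M genes) the gap was 0.893, but their median falls still differed (2.09 and 2.82), so this comparison did not match the depth of the fall, the bound set for it was wrong for that reason, and a deeper fall of the G2/M genes stays open. The percent of the 3-day fall that remained was 48.0 ± 27.3 for S-phase and 65.4 ± 11.5 for G2/M genes (SD, n = 5), with differences per mouse from -7.47 (mouse 9-8) to 33.3 (mouse 9-6), so recovery in proportion to the fall cannot be told apart from a slower return of mitosis genes. The difference between the studies, with 0 vehicle mice of the second among these samples, and resistance itself may each contribute and were not separated.

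The 10 genes with the largest falls from sensitive to resistant tumors, among them KRT79, AWAT2 and CES1, had a median of 20.4 TPM in sensitive, 8.72 in vehicle and 1.12 in resistant tumors. Vehicle mice varied, with medians per mouse of 2.43 TPM (1-5), 3.145 (1-2) and 10.7 to 14.2 in the others. Sensitive mice had 14.3 to 25.5 TPM and resistant mice 0.555 to 2.00. Outer epidermis taken along with the vehicle and sensitive tumors would bring KRT1, LOR and FLG, and these reached at most 0.035 TPM in any of these mice. Skin next to a xenograft is mouse skin, though, and the table holds human symbols with mouse reads set aside in a way not given in the sources used here, so low human values are expected with or without it and skin cannot be told apart from the tumor as the source. In the same mice KRT10 reached 19.8, KRT15 16.9, DSG1 2.31 and SBSN 1.78 TPM (in resistant mice 17.0, 52.7, 0.190 and 0.285), and no list for hair follicle or skin glands was tested. A difference between the 2 studies cannot be told apart from treatment length, with 0 vehicle mice of the second study among these samples. A loss of these transcripts from the tumor cells under prolonged treatment may also explain the pattern and was not tested.

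In 34 of 428 groups of 5 mice checked, 30 for genes and 4 for list scores, 1 mouse stood far from the others of its group; chance gives about 1 in 20, and the sensitive group of 3 was not checked. Vehicle mouse 1-6 stood highest for CDK4 (330 TPM; others 276 to 282), TFF3 (491; 229 to 261), EGR3 (14.6; 2.39 to 3.50) and PDZK1 (95.0; 15.6 to 22.7). Vehicle mouse 1-5 stood lowest for RPS18 (3673 TPM; 4619 to 4965), BTG2 (47.2; at least 99.7), NPM1 (1194; 1421 to 1522) and the ribosomal protein score (11.17; 11.46 to 11.52), and highest for ALDH1A3 (7.90 TPM; 3.96 to 4.64) and IER2 (50.1; 41.8 to 42.7). Vehicle mouse 1-2 stood highest for COX7B (592 TPM; 528 to 542) and lowest for NRARP (8.94; 11.5 to 12.6), CTSB (159; 167 to 170) and TAP1 (23.3; 24.9 to 25.3). Resistant mouse 9-8 stood lowest for CDK4 (239 TPM; 258 to 261), RB1 (18.6; 23.0 to 25.0) and POLA1 (9.38; 14.8 to 16.3), and highest for PLIN1 (0.465; 0.325 to 0.355). Resistant mouse 9-7 stood highest for S100A8 (8.96 TPM; 1.95 to 2.50), B2M (502; 353 to 384), TNFSF10 (21.1; at least 9.55) SOX2 (7.36; 2.03 to 2.22), S100A9 (30.0; 5.80 to 7.39) and GAS5 (626; 518 to 544), and lowest for CD68 (3.77; 8.31 to 10.2), TFF3 (1487; 2382 to 2695) and FHL2 (15.3; at least 26.1). The same mouse stood highest for the scores of the luminal identity (9.06; 8.86 to 8.90), interferon response (4.01; 3.01 to 3.21) and NF-kB response genes (3.91; 3.48 to 3.58). Resistant mouse 9-6 stood highest for PFKFB3 (96.1 TPM; 68.0 to 74.9) and lowest for PSMB9 (0.830; 1.86 to 2.18), and 9-3 lowest for HIST1H2BG (21.1; 32.0 to 37.1) and HIST1H2BC (30.6; 34.3 to 35.5).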

How the results depend on the processing

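No alternative was added after the data were seen. The numbers that follow are for sensitive versus vehicle, resistant versus sensitive and resistant versus vehicle in turn. Across the alternatives, genes taken up singly kept their direction and their side of the threshold in 4663, 4655 and 4739 tests. Of the others, 169, 191 and 131 lost their call, 86, 72 and 47 gained one and 0, 0 and 1 reversed. The reversal was CTSB in resistant versus vehicle tumors, from a fitted -0.15 to 0.00562 with median-of-ratios scaling. The fitted change includes the shift of all genes (median -0.14). List tests kept direction and side of the threshold in 856, 853 and 845 cases, with 24, 29 and 38 calls lost and 14, 12 and 9 gained. List scores did so in 527, 514 and 506 cases, with 0, 0 and 15 calls lost and 0, 13 and 5 gained; in the first 2 comparisons no score was called, so none could lose a call. Unless stated, the cause of a change was not tested. The table gives no depth, so what depth limits is not known, and rescaling within species was not run because the table holds human symbols alone.

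With median-of-ratios scaling sensitive versus vehicle gave 794 genes higher and 1052 lower and resistant versus vehicle 2622 and 2363; 620 genes were lower and 479 higher in both. With quantile normalization the numbers were 938 and 989 at 3 days, 2773 lower in resistant versus vehicle, 632 lower in both, 522 higher in both and 241 higher at 3 days then lower in resistant than in sensitive tumors. In the comparisons with vehicle both scalings raised the median change of all genes to between -0.03 and 0.03. A filter at a mean of 5 TPM left fewer genes and gave 1037 higher in resistant versus vehicle tumors. A fit with only the 2 groups compared gave 239 higher at 3 days, 147 higher in both and 58 higher then lower. Weights per mouse gave 1023 higher and 3390 lower at 3 days, 2036 higher in resistant versus sensitive tumors, 2328 lower in both, 537 higher in both, 928 lower then higher and 303 higher then lower. A libraries alone gave 237 higher at 3 days, 1081 lower in resistant versus sensitive tumors, 131 higher in both and 61 higher then lower. A minimum change of 1 log2 unit, stricter by construction, gave 74 and 356 genes at 3 days, 355 and 152 in resistant versus sensitive and 402 and 424 in resistant versus vehicle tumors; 193 were lower in both, 49 higher in both, 104 lower then higher and 11 higher then lower.

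The fit on 26 libraries gave 199 genes lower at 3 days and then higher in resistant than in sensitive tumors, and with the letter A or B as a replicate block 185. The letters do not pair mice: the A minus B differences of 55 pairs of mice in different groups had 0 correlations over 0.1, and 2 genes differed between letters.

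With an estimated correlation 0 lists were called in sensitive versus vehicle, 0 in resistant versus sensitive and 0 in resistant versus vehicle tumors, with 3, 4 and 4 at an unadjusted p under 0.05; camera called 10, 13 and 13 and fry 11, 14 and 17. In resistant versus vehicle tumors fry called the Notch and Wnt targets (fitted median -0.0302, and 0.11 relative to all genes) in the direction opposite to camera's. It did the same for the apoptosis regulators (fitted median -0.0920, and 0.04 relative to all genes). Camera and fry also differed in direction for other lists there, which neither test called. With median-of-ratios scaling the change in the oxidative phosphorylation score reversed from -0.13 to 0.0226. List scores with that scaling called 13 lists in resistant versus sensitive tumors.

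Leaving out 1 mouse in turn gave 100 (without 6-5) to 542 (without 1-5) genes higher and 801 (6-5) to 1910 (6-4) lower at 3 days. It gave 673 (6-5) to 1589 (1-5) higher and 695 (6-4) to 1977 (1-5) lower in resistant versus sensitive, and 1377 to 1698 higher and 3906 to 4913 lower in resistant versus vehicle tumors. Genes lower in both ranged from 655 (6-5) to 1389 (6-4), higher in both from 65 (6-5) to 338 (6-4), lower then higher from 175 (6-5) to 549 (1-5) and higher then lower from 23 (6-6) to 158 (1-5). Without a sensitive mouse that group has 2 mice.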

Other observations

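The fits on other divisions of the mice into groups of the same sizes were set before the data were examined, and the genes singled out among other cell markers were chosen after their values were seen.

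Luminal identity genes were not called as a list by camera in any comparison, though single members moved. MUC1, a membrane mucin of luminal epithelium, rose from 481 ± 67.0 TPM (SD, n = 3) in sensitive to 2439 ± 562 TPM (SD, n = 5) in resistant tumors, and among 14 tested luminal genes 2 were higher and 5 lower in resistant than in vehicle tumors. Of 12 EMT and mesenchymal genes, 3 were higher and 2 lower in that comparison. Of 7 senescence-associated secreted factors, 3 were higher and 1 lower; TIMP1, an inhibitor of matrix metalloproteinases, rose by 3.05 ± 0.32 (adjusted p = 1.78e-05), and LMNB1 was the one that fell. Of 13 Notch and Wnt targets, 2 were higher and 4 lower: LEF1, a transcription factor of the Wnt pathway, rose by 3.19 ± 0.32 (adjusted p = 1.24e-05), and NRARP, a target of Notch, changed by -1.11 ± 0.11 (adjusted p = 2.53e-06). Of 12 apoptosis regulators, 2 were higher and 4 lower, with the survival gene BCL2 at 1.05 ± 0.12 (adjusted p = 5.24e-05) and BMF, which promotes cell death, at -1.97 ± 0.24 (adjusted p = 2.66e-05). Hippo-YAP targets (2 higher and 4 lower of 14) and fatty acid synthesis genes (2 higher and 4 lower of 14) were likewise not called by camera. Adjusted over the list alone, the numbers in these 7 lists were the same apart from 3 luminal genes higher. Their adjusted p by camera reached 0.876 (Notch and Wnt targets), while fry called the Notch and Wnt targets (adjusted p = 0.0150) and the apoptosis regulators (adjusted p = 0.0174). The exact permutation test on list scores called the senescence-associated factors (score difference 0.43) and the apoptosis regulators (-0.25), each with adjusted p = 0.0189. The senescence-associated score is a mean over 7 genes, of which 4 were above 0 and 3 below as fitted. The rise of TIMP1 makes up most of its difference.

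Among human markers of other cell types, some were low, some moved in opposite directions and some, such as KRT10 (16.3, 14.5 and 15.8 TPM in vehicle, sensitive and resistant tumors) and PNPLA2 (45.1 to 77.6 TPM per mouse), were well expressed and not called. The endothelial marker EGFL7 had 19.5, 18.0 and 10.6 TPM and was lower in resistant than in vehicle tumors (adjusted p = 1.25e-04). COL1A2 had at most 0.355 TPM, DCN 0.070, PTPRC 0.015 and PECAM1 0.060 TPM in any mouse, and how mouse reads were set aside is not given in the sources used here. Of 3 tested fibroblast markers 0 were called in resistant versus vehicle tumors, although FBLN1 was lower in sensitive tumors by -1.88 ± 0.20 (adjusted p = 1.40e-05). Of 6 macrophage and neutrophil markers 2 were higher (CD68 and FCER1G) and 3 lower (CSF1R, S100A8 and S100A9) in resistant than in vehicle tumors; S100A9 averaged 37.9 TPM in vehicle and 11.2 TPM in resistant tumors. Of 5 pericyte and smooth muscle markers 1 was higher (TAGLN) and 1 lower (NOTCH3), of 3 adipocyte markers 1 was higher (CFD) and 1 lower (PLIN1), and of 3 epidermis markers 1 was higher (KRT15) and 1 lower (DSG1). The calls of DSG1 (without 1-4, 1-6 or 1-9), CSF1R (without 1-4, 1-6, 1-9, 9-3, 9-7 or 9-9) and PLIN1 (without 1-4) ended, with adjusted p up to 0.0612, 0.0770 and 0.168 over alternatives. MB, the myoglobin gene, had 125 to 311 TPM per mouse while the muscle gene CKM had at most 0.180 TPM. Adjusted over the list alone the numbers were the same. Camera called none of these marker lists in any comparison, while fry called the fibroblast markers in sensitive versus vehicle (adjusted p = 0.0275), the pericyte markers in resistant versus sensitive (adjusted p = 0.0443) and the epidermis markers in resistant versus vehicle tumors (adjusted p = 0.0367). The exact permutation test on list scores also called the epidermis markers in resistant versus vehicle tumors (adjusted p = 0.0189). Their fitted mean change was 0.62 and their median -0.04, with 1 of 3 members above 0. The upward direction of both calls of this list therefore comes from KRT15.

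Among lists that camera did not call in resistant versus vehicle tumors, 8 of 12 basal and stem-like keratin genes and 13 of 23 oxidative phosphorylation genes were lower and 1 of each higher, also adjusted over the list alone (adjusted p = 0.230 and 0.102; by fry, which tests against no change, 0.00506 and 0.00444; by the exact permutation test on the score 0.0289 for both). The fitted median of the oxidative phosphorylation genes was -0.16 and that of all genes -0.14, so fry's p for this list includes the shift of all genes. The basal and stem-like keratin genes were called with median-of-ratios scaling (adjusted p = 0.0468, range over alternatives 0.00506 to 0.926). So were the ribosomal protein genes (adjusted p = 0.0349, range 0.0349 to 0.890). Without rescaling 0 of these ribosomal genes were called as single genes, and with that scaling RPL3 was (adjusted p = 0.0324).

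Other divisions of the mice into groups of the same sizes were fitted in the same way. The real grouping gave 2212 genes in sensitive versus vehicle tumors, and 1 of 56 divisions, the real one, gave as many (highest other 143). It gave 2977 genes in resistant versus sensitive tumors, matched by 1 of 56 (highest other 239). In resistant versus vehicle tumors it gave 6194, matched by 1 of 100 drawn (highest other 411). This argues against chance for these numbers of genes, as far as 56 or 100 divisions can tell. For the numbers of lists called by camera, 10, 13 and 13, as many were reached in 12 of 56, 7 of 56 and 21 of 100 divisions (highest other 14, 16 and 18), so chance cannot be excluded for how many lists were called.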
